A study of Mus musculus with 12 samples.

How the data were processed

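RNA was measured in 12 libraries of BV2 cells, 3 in each of 4 groups that the labels define by infection with HSV-1 (multiplicity of infection 1, 24 hours) and by treatment with DMSO or 30 nM carfilzomib (CFZ). Poly-A RNA was extracted with TRIzol and made into libraries with a NEBNext Ultra RNA kit, per the labels' protocols. The labels give replicates the numbers 1 to 3 and do not say that they came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

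The deposited gene table holds whole numbers per gene that were not normalized and are taken here as estimated counts. For all 22105 genes compared, the value equalled the sum over the gene's transcripts in the deposited transcript table. How reads were assigned to transcripts was not given in the sources used here. A second deposited table holds FPKM values per gene, normalised for transcript length and depth by the authors. HISAT2 2.1.0, SAMtools 1.9, Subread 2.0.0, featureCounts and the genome build mm10 are named in the submitters' processing notes, with no role or order. The annotation release was not given in the sources used here. The kit as named does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. Members of multi-copy families, such as Usp17l, Pramel, Zscan4 and the histone genes, can share reads and are uncertain one by one.

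The count table had 23177 entries, of which 22105 carried a gene identifier. The other 1072, made up of 1061 assembled loci and 11 transcripts without a gene, were left out of library sizes and tests. They held 1.07, 0.808, 0.599 and 0.630% of the counts on average in uninfected DMSO, uninfected CFZ, HSV-1 DMSO and HSV-1 CFZ. Columns of other samples numbered 0. Coordinates came from GENCODE M21 on GRCm38, the assembly also called mm10, where 21995 of the 22105 identifiers (99.5%) were found.

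The design had assumed raw counts. Because the values were taken as estimated counts and were already whole, the same count test was used without further rounding. edgeR 4.0.16 in R 4.3.3 was run on all 12 libraries in one model with a term per group and no replicate term. Genes were kept by filterByExpr with a minimum count of 10, which left 13006, and scaled by TMM. Dispersions and the quasi-likelihood fit were robust, and the common biological coefficient of variation was 0.0619. The 5 comparisons were infection under DMSO, infection under CFZ, CFZ in uninfected cells, CFZ in infected cells and the interaction, which is the CFZ effect in infected cells minus that in uninfected cells. P-values were two-sided and adjusted by Benjamini-Hochberg over the 13006 genes of each comparison, with a threshold of 0.05. An adjusted p given for a gene is from edgeR's quasi-likelihood test unless another tool is named.

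CPM (counts-per-million) values are the deposited estimated counts divided by the library total after TMM adjustment, given as mean ± SD over 3 libraries. Where a group had no count, the fold is a lower bound against 3 counts over the whole group. With 1 to 3 counts the ratio is given with a 95% counting interval. Intervals and floors cover counting error only. Fitted folds of such genes depend on the prior count and are not given as results. They are printed only for Ifnb1, Adra2b and Iqcn, where an alternative changed the sign of the interaction. List medians are also given with such members set to their bound where this changed them.

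A total of 27 gene lists were fixed before the data were examined, as were the groups, the tests, the alternatives and the rule for named genes. The lists were proteasome subunits, immunoproteasome and MHC class I, chaperones of heat shock factor 1, the unfolded protein response, ATF4 stress targets, NRF2 oxidative stress, autophagy and ubiquitin, interferon-stimulated genes, interferon genes, virus sensing, NF-kB inflammation, inflammatory cell death, apoptosis, p53 targets, DNA replication, mitosis, replication-dependent histones, immediate-early genes, cholesterol synthesis, ribosomal proteins, nuclear oxidative phosphorylation, mitochondrially encoded genes, glycolysis and hypoxia, microglia identity, disease-associated microglia, phagosome and lysosome, and markers of other cell types. The list called proteasome subunits, or proteasome subunit genes, also holds genes of proteasome assembly and regulation, such as Psmg1 and Pomp. Each list was tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and adjusted over the 27 lists within each comparison. Camera with an estimated correlation and fry were alternatives. Counts of members were taken from the adjustment over all genes tested and from one adjusted over the list alone.

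Genes were named by a fixed rule. For each comparison it took the 8 largest positive and 8 largest negative log2 fold changes among genes with an adjusted p below 0.05, a mean CPM of at least 5 in the higher group and no overlap of CPM between the groups. For the interaction the CPM condition applied to any group and the overlap condition was dropped. Predicted or unnamed models and mitochondrially encoded genes were left out of this part. The rule added up to 4 members of each list with the smallest p, and always took 12 genes: Psmb5, Ifnb1, Isg15, Cxcl10, Tnf, Il6, Il1b, Hmox1, Hspa1a, Ddit3, Atf3 and Cdkn1a. A few genes that the rule takes are not reported here. A gene named outside the rule is said to have been chosen after its values were seen.

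The alternatives were DESeq2 1.42.0 with its independent filtering on or off, RLE factors or library size alone in place of TMM, mitochondrially encoded genes left out, no filter, a mean CPM of at least 1, a fit of only the groups compared, the replicate number as a block with and without thinning, and thinning to the smallest total. Others were an added threshold of 1 on the log2 scale, limma with trend and robust settings on log2(FPKM + 1) or log2(FPKM + 0.1) of the deposited FPKM values, and leaving out each library in turn. Overlaps between comparisons that share libraries were set against 20 simulations of groups without a CFZ effect.

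The count test was tested on simulated data with 50 changed genes at each fold. For CFZ in infected cells, on 12571 genes, it recovered 92% at 1.5-fold, 96% at 2-fold and 100% at 4- and 8-fold, and called 6 of 12371 unchanged genes. For the interaction, on 12536 genes, it recovered 74, 92, 100 and 100% and called 11 of 12336. In a simulation of CFZ in infected cells on 13006 genes with 1 list shifted 1.5-fold, camera called that list and 0 of the 26 others. Genes were drawn independently of one another there, so this does not show how camera fares with correlated genes.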

Results

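BV2 is an immortalised mouse microglial cell line. RNA was measured in 12 bulk libraries of BV2 cells that the labels place in 4 groups of 3. According to the labels, cells were left uninfected or were infected with herpes simplex virus 1 (HSV-1) at a multiplicity of infection of 1 for 24 hours. Within each state they received either the vehicle DMSO or 30 nM carfilzomib (CFZ), an irreversible proteasome inhibitor that binds the catalytic subunit encoded by Psmb5. Total counts ranged from 23817601 to 28972964 per library. The group means were 23954347 ± 130570 (SD, n = 3) for uninfected DMSO, 27435873 ± 462659 for uninfected CFZ, 28882684 ± 79392 for HSV-1 DMSO and 28480853 ± 388794 for HSV-1 CFZ. At these depths a count of 0 over a whole group allowed a level of up to 0.0430, 0.0354, 0.0360 and 0.0349 CPM (counts-per-million), in that order. The number of genes with at least 10 counts fell from 13044 ± 75.3 in uninfected DMSO to 12285 ± 59.2, 11606 ± 14 and 11695 ± 20.8 in the other groups. The first principal component held 78.8% of the variance and the second 6.52%. No pair of replicates of a group agreed within sampling noise. Their chi-square per gene ran from 3.58 to 6.79 except for HSV-1 CFZ replicate 1, which stood apart at 11.4 and 11 against replicates 2 and 3, themselves at 4.74. All 12 libraries were kept. Without HSV-1 CFZ replicate 1, CFZ in infected cells gave 3056 genes higher and 3214 lower, against 3064 and 3121 with it.

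Genes with a known response to infection or to proteasome inhibition were read in all 4 groups before any comparison, as a check of the labels. Cxcl10, a chemokine gene induced by interferon (ENSMUSG00000034855, GRCm38 chromosome 5, 92346638 to 92348889), stood at 519 ± 24.1 CPM in libraries labelled uninfected DMSO and 525 ± 35.8 in those labelled uninfected CFZ. It stood at 3.96 ± 0.500 CPM in libraries labelled HSV-1 DMSO and 7.01 ± 0.617 in those labelled HSV-1 CFZ (SD, n = 3 each). Ifnb1, which encodes interferon beta (ENSMUSG00000048806, chromosome 4, 88522025 to 88522774), stood at 3.07 ± 0.277 and 4.31 ± 0.0393 CPM in the libraries labelled uninfected. In those labelled infected it had 2 counts over the DMSO group and 4 over the CFZ group. The cytokine genes Tnf, Il6 and Il1b were likewise high in libraries labelled uninfected. Under DMSO, Tnf read 1064 ± 42.4 CPM against 49.3 ± 2.24 in libraries labelled infected, Il6 115 ± 6.79 against 0.312 ± 0.279, and Il1b 95.2 ± 5.35 against 0.696 ± 0.288. Isg15, a ubiquitin-like gene induced by interferon, read 230 ± 3.74, 251 ± 11.8, 20.9 ± 0.763 and 33.7 ± 1.83 CPM in the order uninfected DMSO, uninfected CFZ, HSV-1 DMSO and HSV-1 CFZ.

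Of 6 genes known to respond to a blocked proteasome, Hspa1a, Ddit3, Atf3 and Hmox1 were lower in the libraries labelled CFZ than in those labelled DMSO in both infection states, Cdkn1a in uninfected cells and Psmb5 in infected cells. In the same order of groups, the inducible chaperone gene Hspa1a read 28.0 ± 0.935, 7.41 ± 1.54, 0.420 ± 0.0745 and 0.117 ± 0.0547 CPM. Ddit3, a stress transcription factor gene, read 123 ± 1.96, 44.6 ± 4.03, 60.0 ± 2.36 and 18.7 ± 0.681 CPM. Atf3, another stress transcription factor gene, read 719 ± 2.43, 356 ± 23.3, 206 ± 6.89 and 134 ± 9.13 CPM. Hmox1, which encodes heme oxygenase, read 431 ± 38.0, 238 ± 9.84, 329 ± 22.8 and 275 ± 30.7 CPM. Its call in infected cells ended without any of 4 libraries, with an adjusted p of up to 0.0966. The cell-cycle inhibitor gene Cdkn1a read 272 ± 3.77, 179 ± 15.0, 132 ± 9.63 and 140 ± 18.4 CPM, with no difference called in infected cells. Psmb5 (ENSMUSG00000022193, chromosome 14, 54614119 to 54618022) read 154 ± 2.0, 168 ± 1.21, 222 ± 7.51 and 179 ± 2.69 CPM, and was called higher with CFZ in uninfected cells. The infection-response genes therefore ran against the infection label, and Hspa1a, Ddit3, Atf3 and Hmox1 against the CFZ label. Groups are named below by their labels, and every direction given rests on those labels.

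**Figure D1:**
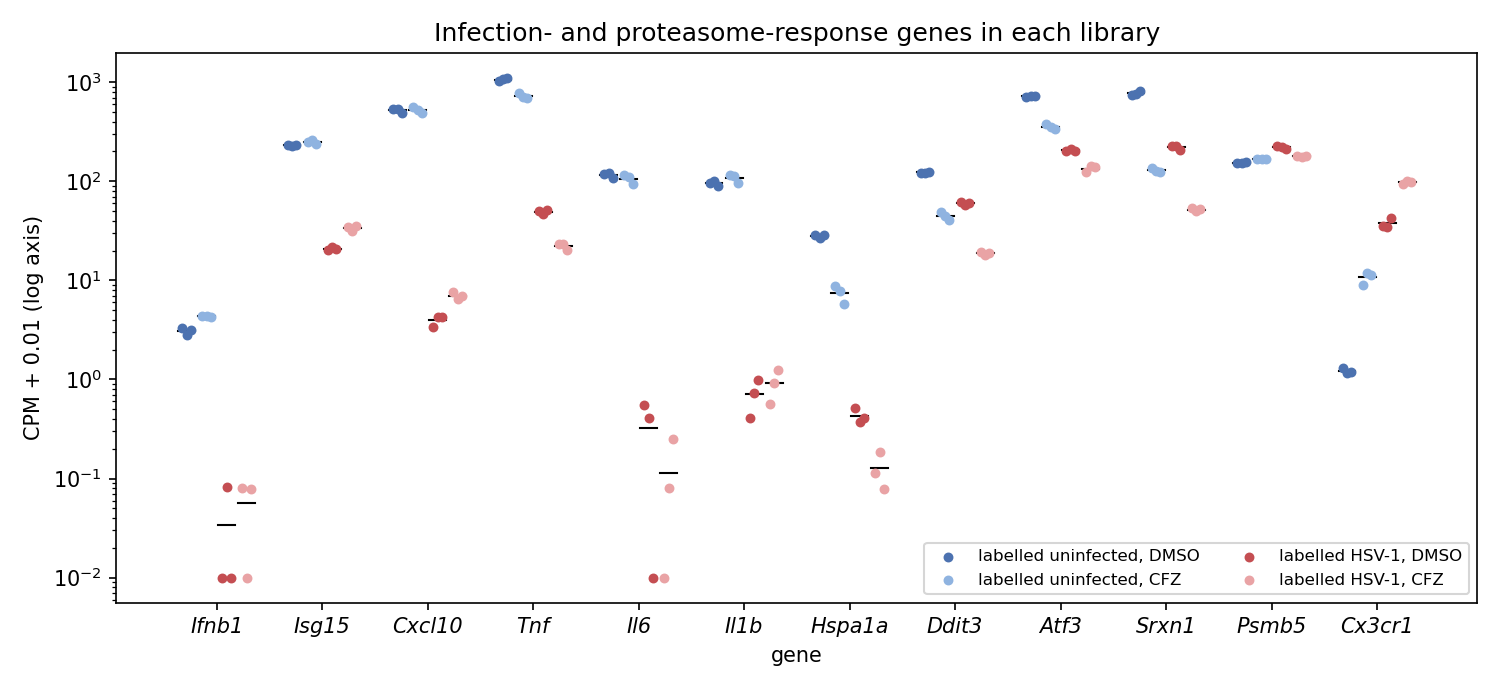
CPM of 12 genes in each of the 12 libraries, with 0.01 added to each value, on a log axis. Each point is a library, colours give the labelled group, and the black bar is the group mean. The interferon and cytokine genes Ifnb1, Isg15, Cxcl10, Tnf, Il6 and Il1b lie lower in all 6 libraries labelled HSV-1, while Cx3cr1 lies higher.

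The first comparison asked what infection changed without the drug. In the libraries labelled HSV-1 DMSO, genes of the interferon response and of inflammation stood far below their level in those labelled uninfected DMSO. Nuclear genes of mitochondrial respiration stood above it. The log2 fold change was -7.03 for Cxcl10, -4.43 for Tnf and -3.46 for Isg15, with adjusted p at or below 9.55e-22 for each in edgeR's quasi-likelihood test. Among 13006 genes tested, 4988 were higher and 5323 lower, of which 1064 and 2336 changed by at least 1 on the log2 scale. With 79.3% of the genes called, few could serve as an unchanged reference for scaling. Here and in the other comparisons, rises and falls are relative to the other RNA in a library. A change in total mRNA per cell would not be seen.

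The largest rise was in Cx3cr1, the fractalkine receptor gene of microglia (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879), from 1.2 ± 0.0757 to 37.6 ± 4.36 CPM, a log2 fold change of 4.96 ± 0.13 (SE). Next came Selenbp1 (4.6), a selenium-binding protein gene, F10 (4.39), the coagulation factor X gene, and Jakmip1 (4.32). They were followed by Selenbp2 (3.73), Ephx1 (3.57), an epoxide hydrolase gene, Bnip3 (3.35), a mitophagy gene induced by hypoxia, and Serpinb1a (3.06). The genes with the most negative fitted fold changes had no count in any HSV-1 DMSO library, so their folds are lower bounds. Their rank depends on the prior count, and genes with counts left could have fallen as far. Csf3, chosen here after its values were seen, stood at 194 to 204 CPM in uninfected DMSO libraries. It stood at 0 to 0.144 CPM in HSV-1 DMSO libraries, a wider ratio than any of the bounds below. Shisa7 stood at 34.7 ± 0.326 CPM in uninfected DMSO and was at least 963-fold lower. Usp17le, a deubiquitinase gene of a multi-copy family (chromosome 7, 104768049 to 104777470), was at least 795-fold lower, and Nefh, a neurofilament gene, at least 765-fold lower. Gpr50, Igf2, Necab2, Usp17lc and Pramel19 were at least 599-, 592-, 476-, 441- and 407-fold lower. Counts of the Usp17l and Pramel families are uncertain for each member, because near-identical copies share reads.

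Of 45 interferon-stimulated genes, 44 fell and 1 rose, with a median log2 fold change of -2.54. Examples were Ifit3 (-6.35), Mx2 (-5.89) and Cmpk2 (-5.72). The exception was Ifi27l2a (1.12), named after its values were seen. Of 41 genes of NF-kB-driven inflammation, 38 fell and 1 rose (median -3.43). The chemokine genes Ccl2 and Ccl5 fell by 4.61 and 4.12 on the log2 scale, from 2704 ± 42.9 to 111 ± 1.26 CPM for Ccl2. Birc3 (0.39), named after its values were seen, was the gene that rose. All 64 measured replication-dependent histone genes fell (median -4.37), with H3c15 at -5.15 and H4c14 at -6.65. The libraries were made from poly-A RNA, so histone RNA without a poly-A tail is not covered here or in the other comparisons. All 25 immediate-early genes fell (median -1.91), among them Ier3 (-2.63) and Junb (-2.11). These 4 lists were called lower by camera, with adjusted p = 0.00285, 0.00285, 0.0131 and 0.0141 with an estimated correlation. Of 73 nuclear genes of oxidative phosphorylation, 67 rose and 1 fell (median 0.94), with Cox7b at 1.83 and Sdhc at 1.66. This list was called higher, with adjusted p = 0.0386 with an estimated correlation. The gene that fell was Cox6b2, a testis-type subunit gene, named after its values were seen.

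The microglia identity list was called higher, with 22 of 27 genes up and 4 down (median 1.19), and adjusted p = 0.266 with an estimated correlation. Csf1r, the receptor gene for colony-stimulating factor 1, and Cst3 gained 1.44 and 1.82. Genes of disease-associated microglia were called higher with 15 of 19 up and 3 down, or 16 and 3 adjusted over the list alone, and also had adjusted p = 0.266 with an estimated correlation. Lpl, a lipoprotein lipase gene, rose from 593 ± 12.6 to 2030 ± 73.3 CPM. Glycolysis and hypoxia genes (19 up, 3 down of 24, median 0.80) and cholesterol synthesis genes (18 up, 2 down of 24, median 0.60) were called higher, with Tpi1 at 1.45, Pfkl at 1.5, Scd2 at 2.05 and Sqle at 1.65. Their adjusted p = 0.296 and 0.266 with an estimated correlation. Proteasome subunit genes (37 up, 3 down of 45, median 0.45) and phagosome and lysosome genes (18 up, 5 down of 25, median 0.54) were called higher. Their adjusted p = 0.374 and 0.476 with an estimated correlation. Psma4 gained 1.05, Psmd14 0.95, Gaa 1.47 and Ctsb 0.90. Mitosis genes (20 up, 4 down of 30, median 0.28) were called higher, with Ccnb2 at 2.52, and the adjusted p = 0.477 with an estimated correlation. Markers of other cell types were called lower, with 8 of 10 down and 1 up. Their fitted median was -4.43, or -3.84 with the members at 0 set to their bound, and they had adjusted p = 0.280 with an estimated correlation. That call also ended in 8 of the 16 other alternatives, with an adjusted p of up to 0.0995. The neuronal tubulin gene Tubb3 fell by 5.21 and the collagen gene Col1a1 was at least 87.6-fold lower.

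The other 14 lists were not called. Among 3 measured interferon genes, all fell. Ifnb1 was 128-fold lower, with a 95% counting interval of 35.0 to 1064 on 2 counts, and Ifna4 at least 35.5-fold lower. The list's median was -5.15 with members at 0 set to their bound. Chaperone genes of heat shock factor 1 split into 10 higher and 10 lower of 22, with Hspa1b at -5.46 and Fkbp4 at 0.83. Their median was 0.02 and their mean -0.48, and the test pointed down. Unfolded protein response genes of the endoplasmic reticulum (15 higher, 9 lower of 25) had a median of 0.23 and a mean of -0.04, and the test pointed up. ATF4 stress targets (8 higher, 14 lower of 24) held the serine synthesis gene Phgdh at 1.74 and Ppp1r15a at -1.91. Oxidative stress genes of NRF2 counted 7 higher and 13 lower of 24, autophagy and ubiquitin genes 16 and 6 of 25, and immunoproteasome and MHC class I genes 4 and 12 of 19. Virus sensing genes (12 higher, 13 lower of 27) had a median of 0.08 against a mean of -0.28, and included Cgas, the cytosolic DNA sensor gene, at -1.30. Inflammatory cell death genes counted 9 higher and 9 lower of 18, apoptosis genes 8 and 15 of 26, and p53 targets 6 and 12 of 22. DNA replication genes (13 and 10 of 30) had a median of 0.08 and a mean of -0.04. Ribosomal protein genes counted 13 higher and 50 lower of 81, and mitochondrially encoded genes 12 and 1 of 13. Apart from the disease-associated list, the counts adjusted over the list alone were the same as those over all genes tested. Another split of the same 6 libraries called 15 lists against 13 for the real groups, so the number of lists called says little by itself. For 79 of the 83 list calls over the 5 comparisons, the estimated correlation gave the highest adjusted p of 17 alternatives, so for these the value printed beside a list is the upper end of its range. For the other 4 the highest value is given beside the list.

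The second comparison asked what infection changed in CFZ-treated cells. In the libraries labelled HSV-1 CFZ, interferon and inflammatory genes were again below their level in those labelled uninfected CFZ, and mitochondrial genes of both genomes were above it. The mitochondrial calls ended with an estimated correlation, each with adjusted p = 0.128. Log2 fold changes were -6.22 for Cxcl10, -5.03 for Tnf, -9.93 for Il6, -6.90 for Il1b and -2.90 for Isg15. In edgeR's test 4339 genes were higher and 4853 lower, 563 and 1647 of them by at least 1 on the log2 scale.

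The genes that rose furthest were Selenbp1 (4.34), Apln (4.24), which encodes the peptide apelin, Klhl3 (3.73), Sema4g (3.63), Cx3cr1 (3.18), Ipcef1 (3.11), Selenbp2 (3.01) and Ephx1 (3.00). Csf3, the gene of granulocyte colony-stimulating factor, fell from 220 ± 24.1 CPM to 0.0462 ± 0.04, on 4 counts over the group. Cxcl2, a neutrophil chemokine gene, fell by 7.60 on the log2 scale. Serpina3f was at least 222-fold lower, Usp17le at least 220-fold, Shisa7 at least 200-fold, Gpr50 at least 157-fold and Usp17lc at least 154-fold.

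Of 45 interferon-stimulated genes 44 fell (median -1.81), and of 41 inflammation genes 40 fell (median -3.19), with Ifit3 at -4.91 and Ccl2 at -5.30. Ifi27l2a rose here as well, by 0.41. Of 64 histone genes 63 fell (median -3.15), and of 25 immediate-early genes 23 fell and 2 rose (median -1.57), among them H3c15 (-3.56) and Fosl1 (-2.63). The 2 that rose were Egr3 (0.61) and Klf4 (0.57), named after their values were seen. These 4 lists were called lower, with adjusted p = 0.00155, 0.000584, 0.0264 and 0.0264 with an estimated correlation. All 13 mitochondrially encoded genes rose (median 0.95), with mt-Atp6 at 1.17, and 64 of 73 nuclear oxidative phosphorylation genes rose (median 0.53), with Cox7b at 1.05. Both lists were called higher, each with adjusted p = 0.128 with an estimated correlation. Glycolysis and hypoxia genes (22 up, 1 down of 24, median 0.77) and microglia identity genes (20 up, 4 down of 27, median 0.77, or 21 and 4 adjusted over the list alone) were called higher, each with adjusted p = 0.247 with an estimated correlation. Disease-associated microglia genes (13 up, 3 down of 19), cholesterol synthesis genes (15 up, 6 down of 24), mitosis genes (17 up, 4 down of 30) and phagosome genes (15 up, 5 down of 25) were called higher. Their adjusted p = 0.281, 0.485, 0.542 and 0.581 with an estimated correlation.

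A further 6 lists were called lower under CFZ. Immunoproteasome and MHC class I genes (1 up, 15 down of 19), unfolded protein response genes (4 up, 16 down of 25) and virus sensing genes (7 up, 16 down of 27) included H2-T22 (-1.04), Hspa5 (-0.85) and Daxx (-1.30). Their adjusted p = 0.281, 0.281 and 0.247 with an estimated correlation. Chaperone genes (4 up, 13 down of 22), apoptosis genes (5 up, 13 down of 26) and p53 targets (7 up, 13 down of 22) included Hspa1b (-5.79), Bcl2l11 (-1.37) and Plk2 (-2.38). Their adjusted p = 0.480, 0.199 and 0.167 with an estimated correlation, and the call of p53 targets also ended in 13 of the 16 other alternatives, with an adjusted p of up to 0.211. Proteasome subunits (18 up, 9 down of 45, median 0.04), ATF4 targets (11 and 12 of 24), NRF2 genes (8 and 11 of 24, or 9 and 11 adjusted over the list alone), autophagy genes (13 and 8 of 25), inflammatory cell death genes (4 and 10 of 18), DNA replication genes (11 and 10 of 30, median 0.02, mean -0.10), ribosomal protein genes (26 and 20 of 81, or 25 and 19 adjusted over the list alone, median -0.01 with a test pointing up), other-cell-type markers (1 and 8 of 10) and the 3 interferon genes (all lower) were not called. Other-cell-type markers had a median of -2.26 and the interferon genes one of -2.33 with members at 0 set to their bound. The call of the interferon gene Ifna13 ended without any of 8 libraries, with an adjusted p of up to 0.208. For the remaining lists the counts adjusted over the list alone were unchanged.

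**Figure D2:**
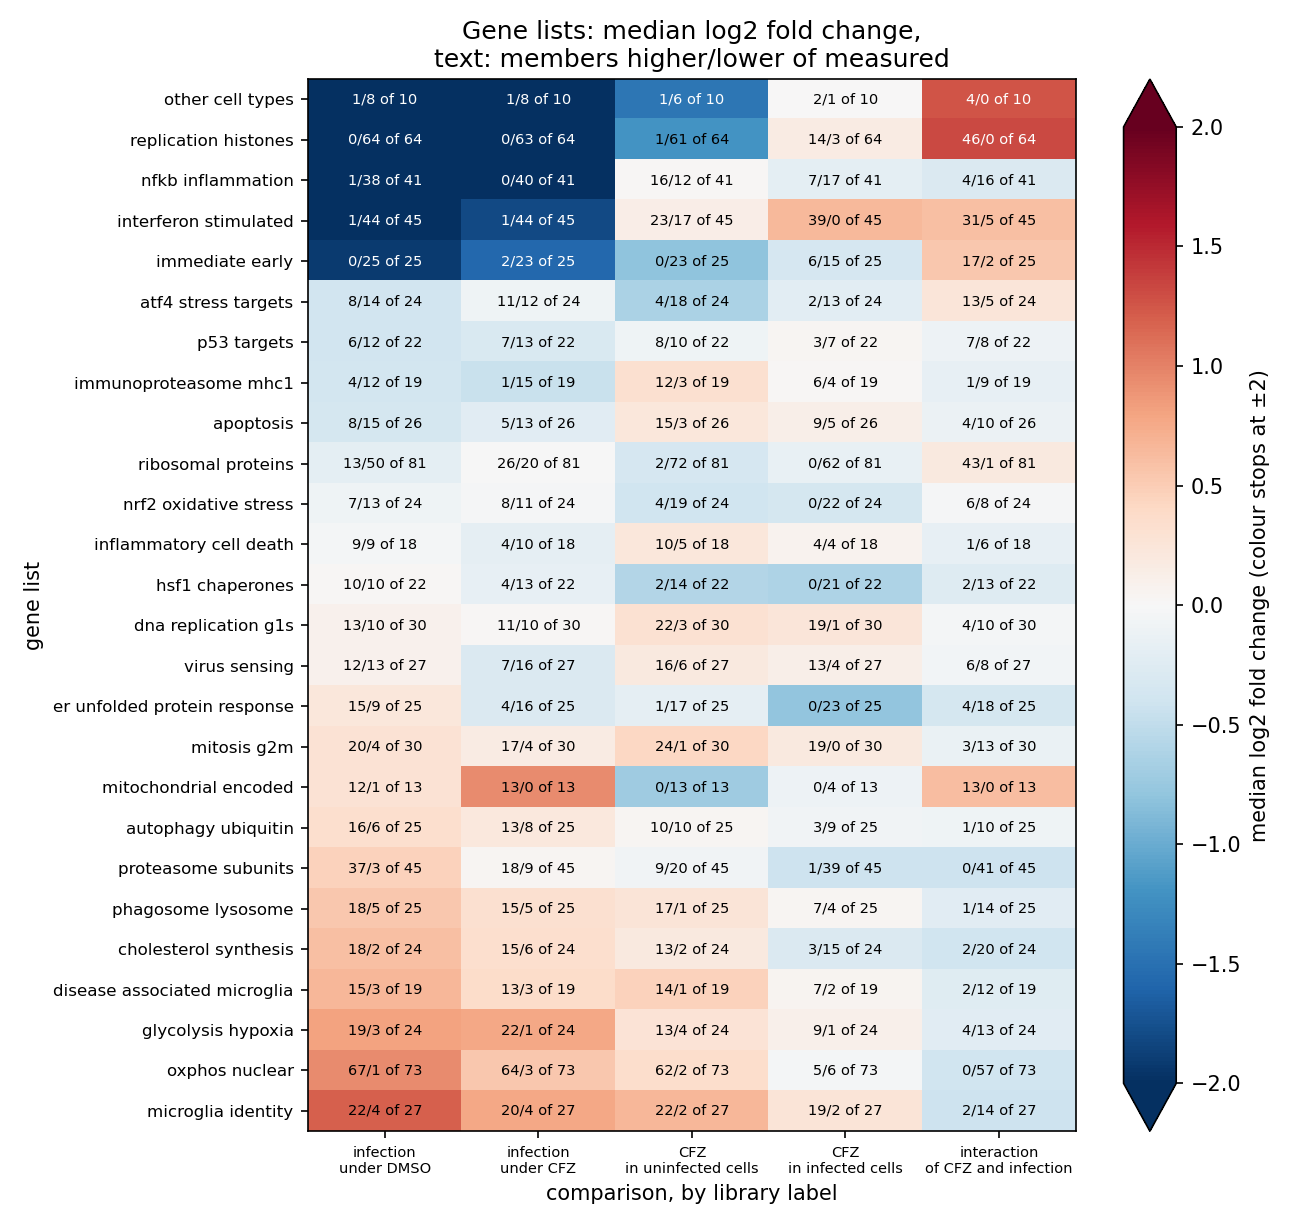
Median log2 fold change of 26 gene lists (vertical axis) in the 5 comparisons (horizontal axis), with the members higher and lower in edgeR's test out of those measured written in each cell. Colours stop at ±2, medians are of fitted values that include members near 0 counts, and interferon genes are left out because 3 were measured. Interferon-stimulated genes are 1 higher and 44 lower of 45 in both infection comparisons and 39 higher of 45 for CFZ in infected cells.

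The next comparison asked what CFZ changed without virus. In the libraries labelled uninfected CFZ, chaperone genes, unfolded protein response genes and ATF4 targets stood lower than in those labelled uninfected DMSO, and microglia identity genes stood higher. No list call held with an estimated correlation in this comparison, where the adjusted p was 0.125 for each of the first 3 and 0.159 for microglia identity genes. Srxn1, an antioxidant gene that encodes sulfiredoxin (ENSMUSG00000032802, chromosome 2, 152105516 to 152111376), fell from 770 ± 35.7 to 129 ± 5.90 CPM, a log2 fold change of -2.57 ± 0.05 (SE) with adjusted p = 1.34e-19 in edgeR's test. Cx3cr1 rose from 1.2 ± 0.0757 to 10.7 ± 1.51 CPM (3.15). In all, 4343 genes were higher and 4243 lower, 315 and 1209 of them by at least 1 on the log2 scale.

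Other genes with large rises were Commd5 (2.29), F10 (2.25), Gda (2.17), a guanine deaminase gene, Kctd12b (2.02), Siglec1 (1.97), a macrophage sialoadhesin gene, and Hp (1.88), which encodes haptoglobin. Those that fell furthest included Slc5a5 (-2.66), the iodide transporter gene, Efnb3 (-2.52), Dio3 (-2.45), Muc3a (-2.32), Shisa7 (-2.31) and the activity-regulated gene Arc (-2.21). Psmb5 rose by 0.12 and Tnf changed by -0.55. Hspa1a, Ddit3, Atf3, Hmox1 and Cdkn1a changed by -1.92, -1.46, -1.02, -0.86 and -0.60, all called. Cxcl10 (0.02, adjusted p = 0.797), Il6 (-0.11, adjusted p = 0.513), Il1b (0.19, adjusted p = 0.0824) and Ifnb1 (0.49, adjusted p = 0.0842) did not pass. Il1b passed without uninfected CFZ replicate 3, HSV-1 DMSO replicate 1 or HSV-1 CFZ replicate 1, with an adjusted p as low as 0.0121, and its fold ran from 0.15 to 0.28 over the libraries left out.

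Stress lists were called lower in the libraries labelled uninfected CFZ, calls that ended with an estimated correlation, where the adjusted p = 0.125 for chaperone, unfolded protein response and ATF4 lists and 0.0820 for NRF2 genes. Chaperone genes (2 up, 14 down of 22, median -0.59) included Hspa8, which went from 6432 ± 425 to 2821 ± 10.5 CPM. Unfolded protein response genes (1 up, 17 down of 25, median -0.18) included the chaperone gene Hspa5 at -1.03. ATF4 targets (4 up, 18 down of 24, median -0.64) included Ppp1r15a at -1.96, and NRF2 genes (4 up, 19 down of 24, median -0.40) included Gclm at -1.37. Autophagy and ubiquitin genes split into 10 up and 10 down of 25, with a median of 0.03, a mean of -0.16 and a test that called the list lower. The adjusted p = 0.245 with an estimated correlation, and the call ended in 9 of the other 16 alternatives as well, with an adjusted p of up to 0.298. The autophagy receptor gene Sqstm1 changed by -1.18. For p53 targets (8 up, 10 down of 22), called lower, the adjusted p = 0.125 with an estimated correlation, and that call also ended in 9 of the other 16, up to 0.194.

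Histone genes (1 up, 61 down of 64, median -1.19), immediate-early genes (0 up, 23 down of 25, median -0.81), ribosomal protein genes (2 up, 72 down of 81, median -0.34) and mitochondrially encoded genes (0 up, 13 down of 13, median -0.72) were called lower. Their adjusted p = 0.0903, 0.105, 0.173 and 0.125 with an estimated correlation. H4c8 changed by -1.58, Dusp1 by -1.83, Rpl12 by -0.84 and mt-Cytb by -0.82. Other-cell-type markers (1 up, 6 down of 10) were called lower, with adjusted p = 0.174 with an estimated correlation, and that call also ended in 10 of the other 16 alternatives, up to 0.177. Nuclear oxidative phosphorylation genes (62 up, 2 down of 73, median 0.36), microglia identity genes (22 up, 2 down of 27, median 0.66) and disease-associated microglia genes (14 up, 1 down of 19, median 0.46) were called higher. Their adjusted p = 0.125, 0.159 and 0.177 with an estimated correlation. Uqcrq gained 0.85, Csf1r 0.69 and Lpl 0.96. Mitosis genes (24 up, 1 down of 30, or 25 and 1 adjusted over the list alone), DNA replication genes (22 up, 3 down of 30) and virus sensing genes (16 up, 6 down of 27) were called higher. Their adjusted p = 0.173, 0.486 and 0.173 with an estimated correlation. Ccnb2 gained 1.44, Tk1 0.83 and Ikbke 1.22. Phagosome genes (17 up, 1 down of 25), cholesterol synthesis genes (13 up, 2 down of 24) and glycolysis genes (13 up, 4 down of 24) were called higher, with adjusted p = 0.336, 0.421 and 0.470 with an estimated correlation.

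Lists not called were proteasome subunits (9 up, 20 down of 45), immunoproteasome genes (12 and 3 of 19, or 12 and 4 adjusted over the list alone), interferon-stimulated genes (23 and 17 of 45), the interferon genes (0 and 2 of 3), inflammation genes (16 and 12 of 41, median 0.02, mean -0.06), inflammatory cell death genes (10 and 5 of 18) and apoptosis genes (15 and 3 of 26, or 16 and 3 adjusted over the list alone). Of the 2 interferon genes called lower, Ifna13 lost its call without any of 5 libraries, with an adjusted p of up to 0.107. Within the interferon-stimulated list, Mx2 and Rsad2 changed by -1.46 and -1.23. For the other lists the counts adjusted over the list alone were unchanged. Another split of the 6 libraries called 18 lists against 20.

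The comparison in the title of the series asked what CFZ changed in infected cells. In the libraries labelled HSV-1 CFZ, genes of the proteasome, of chaperones and of the oxidative stress response were lower than in those labelled HSV-1 DMSO, and interferon-stimulated genes were higher. Gdf15, a stress-induced cytokine gene, went from 63.6 ± 7.06 to 12.3 ± 0.252 CPM (-2.37). Maf, a macrophage transcription factor gene (ENSMUSG00000055435, chromosome 8, 115682942 to 115707794), rose from 7.02 ± 2.01 to 45.4 ± 8.06 CPM (2.69 ± 0.22 SE, adjusted p = 5.94e-06 in edgeR's test). In all, 3064 genes were higher and 3121 lower, 236 and 154 of them by at least 1 on the log2 scale. Higher genes were 49.5% of those called with TMM scaling and 62.9% with library size alone. In uninfected cells the corresponding shares were 50.6% and 59.7%.

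Other genes that rose furthest were Bmf (2.16), a pro-apoptotic gene, Egr3 (2.1), Apln (1.85), Ddx60 (1.70), Ipcef1 (1.69), Maml2 (1.67) and the antiviral gene Mx1 (1.63). Genes that fell furthest included Fosl1 (-2.13), Srxn1 (-2.10), Phlda1 (-1.94), Plk3 (-1.76), Ddit3 (-1.68) and the chaperone gene Hsph1 (-1.63). Isg15 and Cxcl10 rose by 0.69 and 0.83, while Psmb5, Tnf, Hspa1a and Atf3 changed by -0.31, -1.15, -1.81 and -0.62, all called. The call of Hspa1a, low in both groups, ended with limma on log2(FPKM + 1), at -0.12 with adjusted p = 0.299. Cdkn1a (0.08, adjusted p = 0.510), Il6 (-1.54, adjusted p = 0.292) and Il1b (0.38, adjusted p = 0.410) did not pass. Il6 passed without HSV-1 DMSO replicate 3, at -3.0 with adjusted p = 0.0211. Ifnb1 was 1.94-fold higher with a counting interval of 0.278 to 21.4, so no difference was detectable at this depth.

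Of 45 genes on the proteasome subunit list, 39 fell and 1 rose, with a median of -0.41. The gene that rose was the assembly factor gene Psmg1 (0.18, named after its values were seen). Psmd11 changed by -1.10 and Adrm1 by -1.20. Of 22 chaperone genes 21 fell and 0 rose (median -0.62), with Hspa8 at -1.40 and Hsp90aa1 at -0.66. Of 25 unfolded protein response genes 23 fell and 0 rose (median -0.79), with Hspa5 at -1.45 and Manf at -1.04. Of 24 NRF2 genes 22 fell and 0 rose (median -0.35), with Sqstm1 at -1.51 and the thioredoxin reductase gene Txnrd1 at -1.01. These lists were called lower, with adjusted p = 0.0431, 0.0258, 0.00599 and 0.00599 with an estimated correlation. Of 45 interferon-stimulated genes 39 rose and 0 fell, or 41 and 0 adjusted over the list alone (median 0.64), with Rtp4 at 1.52 and Cmpk2 at 1.46. This list was called higher, with adjusted p = 0.0263 with an estimated correlation.

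Autophagy genes (3 up, 9 down of 25), ATF4 targets (2 up, 13 down of 24), inflammation genes (7 up, 17 down of 41, or 8 and 17 adjusted over the list alone) and immediate-early genes (6 up, 15 down of 25) were called lower. Their adjusted p = 0.0636, 0.254, 0.309 and 0.309 with an estimated correlation. Ubb changed by -1.04, Nupr1 by -0.73, Ccl3 by -1.22 and Dusp1 by -1.5. Cholesterol synthesis genes (3 up, 15 down of 24) and ribosomal protein genes (0 up, 62 down of 81, or 0 and 66 adjusted over the list alone) were called lower, with adjusted p = 0.309 and 0.455 with an estimated correlation. Virus sensing genes (13 up, 4 down of 27), DNA replication genes (19 up, 1 down of 30), mitosis genes (19 up, 0 down of 30), microglia identity genes (19 up, 2 down of 27) and disease-associated microglia genes (7 up, 2 down of 19) were called higher. Their adjusted p = 0.273, 0.528, 0.309, 0.309 and 0.609 with an estimated correlation. Pml gained 0.72, E2f1 0.60, Plk1 0.44, Mertk 1.18 and Clec7a 0.80.

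Lists not called were immunoproteasome genes (6 up, 4 down of 19), the interferon genes (0 and 0 of 3), inflammatory cell death genes (4 and 4 of 18, median 0.08 and mean 0.11 with a test pointing down), apoptosis genes (9 and 5 of 26), p53 targets (3 and 7 of 22, median 0.03, mean -0.16), histone genes (14 and 3 of 64, or 14 and 2 adjusted over the list alone), oxidative phosphorylation genes (5 and 6 of 73, or 1 and 3), mitochondrially encoded genes (0 and 4 of 13, or 0 and 3), glycolysis genes (9 and 1 of 24, or 10 and 2), phagosome genes (7 and 4 of 25) and other-cell-type markers (2 and 1 of 10, median 0.00, mean -0.29, test pointing up). Another split of the 6 libraries called 14 lists against 16 for the real groups.

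**Figure D3:**
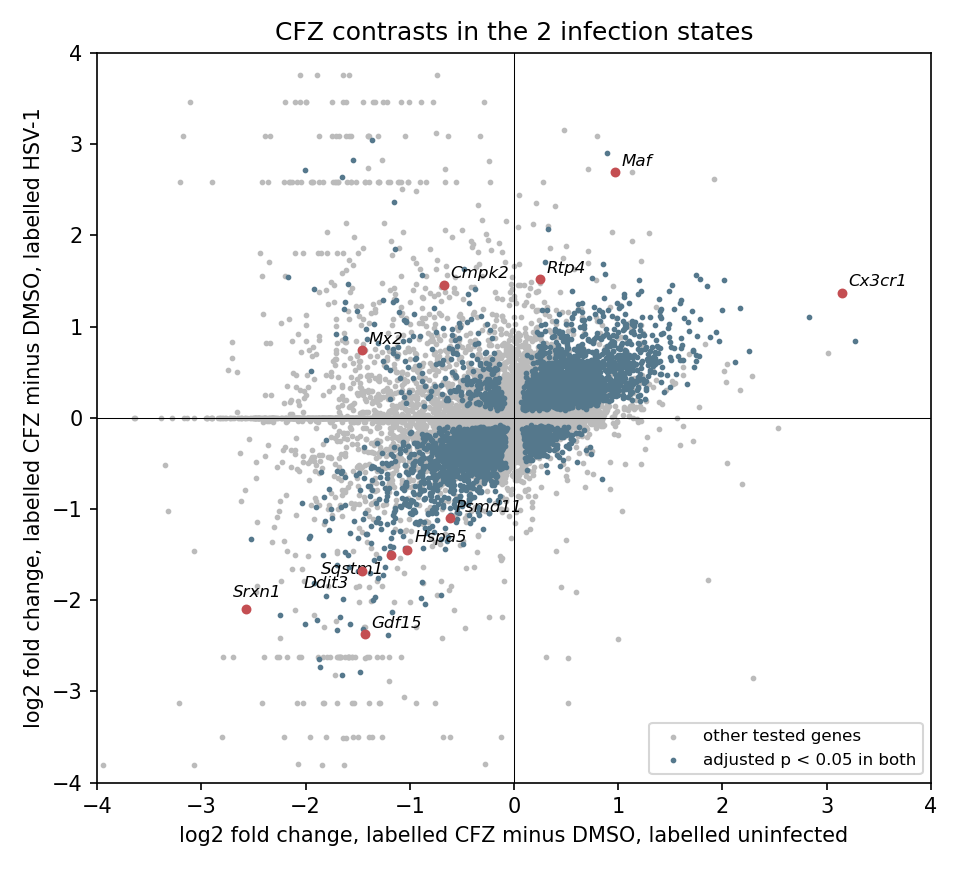
Log2 fold change of CFZ against DMSO in libraries labelled uninfected (horizontal axis) and in libraries labelled HSV-1 (vertical axis), a point per gene, with blue points called in both and red points named. The axes stop at ±4, which leaves out 70 genes, and the horizontal stripes are genes near 0 counts in libraries labelled HSV-1, whose fitted folds depend on the prior count. Ddit3 and Srxn1 lie below 0 in both, and Cmpk2 and Mx2 lie below 0 in uninfected and above 0 in infected cells.

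The last comparison asked whether the CFZ effect differed with infection. The interaction was positive for 1948 genes and negative for 3206, 472 and 60 of them by at least 1 on the log2 scale. No interaction call of a list held with an estimated correlation. Proteasome subunit genes had 0 positive and 41 negative interactions of 45 (median -0.41, adjusted p = 0.119 with an estimated correlation), led by Psmd14 (-0.71) and Psmd1 (-0.64). Oxidative phosphorylation genes (0 and 57 of 73, median -0.40) and unfolded protein response genes (4 and 18 of 25, median -0.35) were also negative, with Uqcrq at -0.89 and Manf at -0.80, and adjusted p = 0.0793 and 0.119 with an estimated correlation. Interferon-stimulated genes (31 and 5 of 45, median 0.60), histone genes (46 and 0 of 64, median 1.33) and mitochondrially encoded genes (13 and 0 of 13, median 0.61) were positive, with Cmpk2 at 2.13, H2bc21 at 1.39 and mt-Nd4 at 0.72, and adjusted p = 0.0793, 0.0793 and 0.112 with an estimated correlation. Adjusted over the list alone, the counts were 1 and 42, 1 and 59, 4 and 18, 32 and 5, 48 and 0, and 13 and 0, in the order given.

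A further 10 lists were called. Chaperone genes (2 and 13 of 22), inflammation genes (4 and 16 of 41), mitosis genes (3 and 13 of 30), cholesterol synthesis genes (2 and 20 of 24), microglia identity genes (2 and 14 of 27), disease-associated microglia genes (2 and 12 of 19) and phagosome genes (1 and 14 of 25) were negative, with Ccl4 at -1.16, Ccnb2 at -1.16, Fdps at -1.13 and Lpl at -0.94. Their adjusted p = 0.495, 0.404, 0.546, 0.119, 0.362, 0.368 and 0.405 with an estimated correlation. ATF4 targets (13 and 5 of 24), immediate-early genes (17 and 2 of 25) and ribosomal protein genes (43 and 1 of 81) were positive, with Ddit4 at 1.5, Ier3 at 0.74 and Rpl12 at 0.66, and adjusted p = 0.362, 0.194 and 0.362 with an estimated correlation. Lists not called were immunoproteasome genes (1 and 9 of 19), NRF2 genes (6 and 8 of 24, median -0.02, mean 0.01), autophagy genes (1 and 10 of 25), the interferon genes (0 and 0 of 3), virus sensing genes (6 and 8 of 27), inflammatory cell death genes (1 and 6 of 18), apoptosis genes (4 and 10 of 26), p53 targets (7 and 8 of 22, median -0.09, mean 0.02), DNA replication genes (4 and 10 of 30), glycolysis genes (4 and 13 of 24) and other-cell-type markers (4 and 0 of 10). Adjusted over the list alone, the counts changed to 4 and 17 for inflammation, 3 and 14 for mitosis, 3 and 16 for microglia identity, 2 and 13 for disease-associated microglia, 13 and 6 for ATF4 targets, 18 and 2 for immediate-early, 44 and 1 for ribosomal protein, 3 and 9 for immunoproteasome, 7 and 9 for p53 and 6 and 10 for DNA replication genes.

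Across the 13006 genes, the CFZ effects in the 2 infection states had a Pearson r of 0.209 and a Spearman rho of 0.425. Genes are not independent replicates, so no p is given. The Pearson value was 0.0640 with no filter on low counts and 0.415 with a mean CPM of at least 1. Of the genes called in both, 2149 were higher in both, 1976 lower in both and 617 opposite, so 87.0% had the same sign. Independent lists would share 1023 higher and 1018 lower genes. Both contrasts come from separate libraries.

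Of the genes higher in libraries labelled HSV-1 DMSO, 961 were lower with CFZ, where independent lists would share 1197, and 1784 were higher, where they would share 1175. Of the genes lower there, 780 were higher with CFZ against 1254 for independent lists, and 1625 were lower against 1277. In 20 simulations of all 12 libraries without a CFZ effect in infected cells, the means were 0.15, 0.2, 0 and 0.05 genes in the same order. A mean of 0.25 genes was called lower and 0.25 higher with CFZ there. Overlaps near 0 were thus fixed in advance and give no baseline for the observed ones. Shared HSV-1 DMSO libraries enter both contrasts with opposite sign. The covariance of the fold changes was -0.0919, against a mean of -0.0548 and a range of -0.0780 to -0.0252 in the simulations. Their Pearson r of -0.0707 was closer to 0 than the simulated mean of -0.0841 and lay within the simulated range of -0.121 to -0.0402.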

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

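The interaction tests were planned before the data were examined, and the split of the interaction by libraries exchanged was read after the result was seen. The CFZ effect differed between libraries labelled infected and uninfected for 1948 genes with a positive and 3206 with a negative interaction in edgeR's test. This difference between the infection states is what singled out each result given here, and the interaction keeps its sign if both labels are exchanged together and takes the opposite sign if either is exchanged alone.

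Named genes with a strongly negative interaction included Jakmip1 (-2.44), Cx3cr1 (-1.78), Tnip3 (-1.52), F10 (-1.52) and Gpr84 (-1.52). Negative values were also called for Siglec1 (-1.12), a sialoadhesin gene, Hp (-0.99), Gda (-0.96) and Kctd12b (-0.50), which had risen with CFZ in uninfected cells. Among genes that fell with CFZ in infected cells, Phlda1 (-1.24), Fosl1 (-0.96), Gdf15 (-0.94), Plk3 (-0.45) and Hsph1 (-0.40) were negative. Positive values were called for Apln (3.00), Slc5a5 (2.72), Bmf (2.24), Mx1 (2.1), Egr3 (2.06), Arc (1.87), Maf (1.73), Maml2 (1.66), Ddx60 (1.40), Efnb3 (1.2) and Srxn1 (0.48). Slc5a5 stood at 0 to 0.29 CPM and Arc at 0.11 to 0.43 in libraries labelled infected. Both had little room for a further fall with CFZ there. Of the genes always named, Cxcl10 (0.81), Cdkn1a (0.68), Hmox1 (0.60), Isg15 (0.56) and Atf3 (0.40) were positive, and Tnf (-0.59) and Psmb5 (-0.43) negative. Ddit3 was at -0.22, and its adjusted p of 0.0436 rose to as much as 0.122 without a library, with the call ending in 9 of the 12 cases. With limma on log2(FPKM + 1), which shrinks the folds of low genes, the calls of Jakmip1 (-0.46, adjusted p = 0.121), Cx3cr1 (-0.24, adjusted p = 0.140) and Ddit3 (-0.20, adjusted p = 0.0617) ended.

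Other named genes had at most 3 counts in a group labelled infected, so their adjusted p is given without a fold. Nefh stood at 27.5, 6.24, 0 and 0.186 CPM in uninfected DMSO, uninfected CFZ, HSV-1 DMSO and HSV-1 CFZ, with adjusted p = 2.28e-06. The adjusted p was 0.0213 for Necab2, 0.0235 for Adra2b, 0.0257 for Usp17la, 0.0264 for Iqcn, 0.0279 for Slfn14, 0.0300 for Cwc22rt3, 0.0354 for Zscan4b, 0.0354 for Atp1b2 and 0.0384 for Rbpjl. Each of these 9 calls ended without at least 1 library. For Necab2 that was HSV-1 CFZ replicate 1 and for Usp17la HSV-1 CFZ replicate 3, where both reached an adjusted p of 1.00. The highest adjusted p was 0.0618 for Adra2b, whose interaction also changed sign on the FPKM scale as did that of Iqcn, 0.0642 for Iqcn, 0.136 for Cwc22rt3 and 1.00 for Slfn14, Zscan4b, Atp1b2 and Rbpjl. Of the genes called positive, 62 had at most 3 counts in a group, and of those called negative, 9.

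Of the 16 lists called, 0 kept the call with an estimated correlation. Their median interaction was 1.33 for histones, 0.61 for mitochondrially encoded genes, 0.60 for interferon-stimulated genes, 0.54 for immediate-early genes, 0.25 for ATF4 targets and 0.19 for ribosomal proteins. It was -0.41 for proteasome subunits, -0.41 for microglia identity, -0.40 for oxidative phosphorylation, -0.40 for cholesterol synthesis, -0.35 for the unfolded protein response, -0.28 for inflammation, -0.26 for chaperones, -0.25 for disease-associated microglia, -0.22 for phagosome genes and -0.14 for mitosis genes.

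Other splits of the same libraries were counted for each comparison. For the interaction, 1 of 100 splits gave as many genes as the real 5154, and this was the real split itself. The highest other gave 4489. Such a share had been predicted to exclude chance, but the other splits mixed CFZ and DMSO libraries within an infection state. These libraries differed in both states with or without an interaction, so the gene count cannot decide on chance. The highest other splits exchanged 2 of the 3 infected-labelled libraries between CFZ and DMSO and 0 uninfected ones, so they kept the CFZ difference between uninfected libraries by construction. As many lists as the real 16 were called by 23 of 100 splits, with a highest other of 19, so chance was not excluded for the list count. The 2-group comparisons had 10 splits each, too few for a share under 0.05. Their real and highest other values were 10311 and 0 genes for infection under DMSO, 8586 and 0 for CFZ in uninfected cells, 6185 and 1 for CFZ in infected cells and 9192 and 0 for infection under CFZ, each reached by 1 split. For lists they were 13 and 15, reached by 9 splits, then 20 and 18, 16 and 14, and 18 and 17, each reached by 1.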

How the results depend on the processing

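All alternatives given here were planned before the data were examined. Of the values for named genes under alternatives, 11539 kept their direction and side of the threshold, 118 kept the direction and lost the call, 23 gained one and 20 changed sign. For lists 1277 kept the call and 134 lost it, and for counts and correlations 459 moved by less than their limit and 23 by more. Of 83 list calls with 17 alternatives each, 14 were kept in all, 56 were lost only with an estimated correlation, 13 with it and another, and 0 only with another. The estimated correlation gave the highest adjusted p for 79 of the 83. Calls that also ended under other alternatives, apart from those given with their list, were cholesterol synthesis with CFZ in uninfected cells (1 of 16, up to 0.0690), disease-associated microglia with CFZ in infected cells (3, up to 0.0810), and for infection under CFZ chaperones (2, 0.0560), mitosis (1, 0.0666), cholesterol synthesis (2, 0.0788) and phagosome genes (1, 0.0736). For the interaction they were chaperones (2, 0.0971) and mitosis (4, 0.117). The cause was not tested for any change given here except where the alternative's construction gives it.

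With an estimated correlation the lists called higher numbered 1 for infection under DMSO, 0 for CFZ in uninfected cells, 1 for CFZ in infected cells, 0 for infection under CFZ and 0 for the interaction, and the lists called lower 0 for CFZ in uninfected cells, 4 for CFZ in infected cells, 4 for infection under CFZ and 0 for the interaction. Fry called 15 lists lower for infection under DMSO, and a mean CPM of at least 1 left 5 lists higher for infection under CFZ. The correlation of the CFZ effects was 0.0640 with no filter and 0.415 with a mean CPM of at least 1. Asking for a log2 fold change of at least 1 as well, which by construction lowers the counts, left 1064 genes higher and 2336 lower for infection under DMSO, 315 and 1209 for CFZ in uninfected cells, 236 and 154 for CFZ in infected cells, 563 and 1647 for infection under CFZ and 472 and 60 for the interaction.

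Values that changed sign belonged to genes not called or near 0 counts. Cxcl10 in uninfected cells was at -0.00703 with RLE factors and -0.00704 with DESeq2 without independent filtering, and from -0.0273 to 0.0733 when a library was left out. With limma on log2(FPKM + 1) and log2(FPKM + 0.1), the interaction was 0.64 and 1.07 for Adra2b, 0.85 and 1.13 for Iqcn, and -0.43 and -0.21 for Ifnb1, and with the first also -0.11 for Il1b. Leaving out a library gave interactions of -0.16 to 2.97 for Ifnb1, -0.12 to 0.50 for Il1b and -0.31 to 0.36 for Hspa1a, and -0.0204 to 0.172 for Cdkn1a with CFZ in infected cells.

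Leaving out each library gave 4858 to 4989 genes higher and 5198 to 5813 lower for infection under DMSO, 4085 to 4497 and 3781 to 4452 for CFZ in uninfected cells, 2605 to 3056 and 2752 to 3214 for CFZ in infected cells, 3957 to 4357 and 4818 to 5099 for infection under CFZ and 1660 to 1939 and 2952 to 3450 for the interaction. The call of Isg15 with CFZ in uninfected cells (0.13) ended without uninfected DMSO replicate 2 or uninfected CFZ replicate 2, with an adjusted p of up to 0.0797. That of Hmox1 with CFZ in infected cells ended without any of 4 libraries, up to 0.0966.

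The replicate numbers gave no clear pairing of the samples: 0 of 18 same-number pairs had a correlation of deviations over 0.1, with a range of -0.05 to 0.09, and 7 of 12 libraries correlated best with their own number. Between HSV-1 DMSO and HSV-1 CFZ, same-number pairs were at 0.095, 0.063 and 0.080 and the other pairs at -0.110 to 0.035. Weak pairing is therefore not excluded there. With the number as a replicate block, 5008 genes were higher and 5315 lower for infection under DMSO, 4386 and 4210 for CFZ in uninfected cells, 3098 and 3156 for CFZ in infected cells, 4364 and 4849 for infection under CFZ and 1984 and 3335 for the interaction.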

Other observations

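The tests of strand-controlled read-in, of head-to-head neighbours, of expressed genes within 50 kb and of CFZ acting only through infection, and the list of 2-cell-stage genes, were chosen only after results they bear on were seen. Genes normally active in the 2-cell-stage mouse embryo, of the Zscan4, Usp17l, Pramel, Tcstv, Tdpoz and Obox families with Duxf3 and Zfp352, summed to 330 ± 16.2 CPM in libraries labelled uninfected DMSO (85 genes, SD, n = 3). They summed to 116 ± 13.8 in uninfected CFZ, 23.7 ± 1.29 in HSV-1 DMSO and 19.5 ± 0.570 in HSV-1 CFZ. Pramel12, named after its values were seen, made up nearly all of the sums in libraries labelled infected, at 22.7 to 25.1 CPM in HSV-1 DMSO and 18.6 to 19.8 in HSV-1 CFZ. Of 44 that passed the expression filter, 44 were lower for infection under DMSO, with a median of -6.98 when the 43 at 0 were set to their bound. For CFZ in uninfected cells 43 were lower (median -1.76), and for infection under CFZ 43 were lower (-5.15, with 38 at their bound). Reads of these families can be shared between copies, so single members are uncertain. The list leaves out some family members, such as Zscan4-ps1, Zscan4-ps2 and Zscan4-ps3, so the sums cover the listed genes only.

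A list of 14 genes, mostly of ubiquitin shuttling and the p97 segregase, was fixed before its values were seen. It also holds genes of other roles, such as the transcription factor gene Mafg and the deubiquitinase gene Usp5. With CFZ in uninfected cells 10 were lower and 1 higher (median -0.34), and in infected cells 13 lower and 1 higher (median -0.53). Zfand2a, which encodes a proteasome-associated zinc finger protein, changed by -1.54 and -1.13, and the p97 cofactor genes Nploc4 and Ufd1 by -0.62 and -1.08 and by -0.62 and -0.99.

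Infection-response genes were low in libraries labelled infected, and depth was argued against because 100% of the 44 interferon-stimulated genes called lower stayed so after thinning. Transcription past gene ends is known from HSV-1 infection, and exchanged infection labels had been predicted to put a read-in index of weak genes behind expressed ones below 0, but it was 0.358 (SE 0.109) under DMSO and 0.212 (SE 0.0885) under CFZ, which went against that explanation as predicted. After this was seen that reading was withdrawn, because 42 weak genes head to head with an expressed gene, whose transcription runs away from them, and with no expressed gene ending towards them within 50 kb, stood higher still over distant genes, by 1.56 (SE 0.220) and 1.04 (SE 0.152), so distant genes were no valid baseline. An index against all head-to-head neighbours, chosen afterwards, was -0.907 (SE 0.216) under DMSO and -0.614 (SE 0.155) under CFZ, but these neighbours differ from distant genes without read-in and are no neutral baseline either, so it decides nothing. The genes tested all carried mouse identifiers, so viral RNA could not be read as a check of the infection labels. Exchanged infection labels and correct labels with shutoff of host genes both stay open. An exchange of infection and CFZ labels together, which would reverse the order of the groups, was not tested and stays open too.

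Chaperone genes of heat shock factor 1 were called lower in libraries labelled CFZ, 14 of 22 in uninfected cells, where the list call ended with an estimated correlation (adjusted p = 0.125), and 21 of 22 in infected cells, where it held (adjusted p = 0.0258). Depth was argued against, since 100% of the chaperone genes called lower stayed lower after thinning in both infection states. By the labels, the 14 chaperone genes called lower in uninfected cells did not differ with CFZ in infected cells alone. The rule for an action of CFZ only through infection was set after these counts were seen. It restates them and was no independent test. The median of -0.53 of the ubiquitin shuttle list in infected cells had the sign that exchanged CFZ labels had been predicted to give. A lasting fall of these genes under correct labels would give the same sign, so the sign cannot tell them apart. An exchange of CFZ labels stays open. A lasting fall of these genes at this dose and time was not tested and stays open too.

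A set of 217 genes had at most 3 counts over the 6 libraries labelled infected and at least 1 CPM in uninfected DMSO. The opposite was shown by 0 genes. Of the 217, 36 were on the 2-cell-stage list. That list is not complete, and Zscan4-ps1, Zscan4-ps2 and Zscan4-ps3 were in the set without being on it. With uninfected CFZ in place of uninfected DMSO, 71 genes were counted. In thinned libraries 97.2% of the 217 genes still met the first 2 conditions, an outcome that thinning had little room to change. Depth was argued against by the mean totals, which were higher in libraries labelled infected under both treatments. Of 215 with usable coordinates 2.79% began within 5 kb downstream of an expressed gene on their strand, against 8.93% of 2800 other weak genes (Fisher's exact p = 0.000833), a lower share that had been predicted to count against read-in but decides nothing, since genes beside expressed ones differ from distant ones without it. Read-in over up to 50 kb was argued against as the cause for all of them, since 78.1% had no gene of at least 20 CPM that close, upstream on their strand or ending towards them, while read-in for the rest or over longer distances stays open. No biological explanation was tested beyond the labelled groups, and infection stays open as one, under either reading of the labels.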
